A study of Mus musculus with 67 samples.

How the data were processed

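Single cells cultured from mouse aorta were measured by RNA sequencing, 22 cells at passage 1 and 45 at passage 2, 1 library per cell. Per the submitters' processing notes, cells were captured on a C1 system, dual-indexed libraries were made with Nextera XT reagents, and BWA, SAMtools, HTSeq and DESeq were used with the GRCm38 genome, with no versions given. The signal values in the deposited table are gene counts that the authors divided by 1 size factor per cell with DESeq. The handling of multi-mapping reads and of strand was not given in the sources used here. Values of Gapdh, ribosomal protein genes and the actin genes, such as Acta2, Actg2, Acta1 and Actb, are therefore uncertain.

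The table held 39179 gene rows, of which 20000 had a read in at least 1 cell and 37607 had a symbol in the GENCODE M21 annotation. Reads were recovered by dividing each column by its smallest step, and 100% of 509576 values above 0 lay within 0.001 of a whole number (largest distance 1.87e-05). The deposited factors equalled median ratio factors over the 747 genes with a read in every cell to within 7.24e-08 percent. Of values above 0, 26.7% were 1 to 3 reads, so shares of cells are given with any read, at a value of at least 10 and after thinning to 500000 reads, which removed no cell. The median share of reads in mitochondrially encoded genes was 5.37% and 5.01%, and that in the 50 highest genes of each cell 19.1% and 23.9%. No doublet caller was run on 67 cells.

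Genes were kept with a mean of at least 10 in a passage and a read in at least 25% of its cells, which left 8682 genes and 97.8% of reads. The log2 ratio compared means over cells, log2(mean + 1) at passage 2 minus that at passage 1, which understates differences of genes with low values. For each gene the percentage of passage 1 and passage 2 cell pairs with the higher value at passage 2 was also computed. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Because the labels name no animal or culture, the cells of a passage count as 1 sample, and a count test on the recovered reads was not run for that reason. Shares have exact Clopper-Pearson 95% intervals, summed reads exact Poisson intervals and ratios of summed reads exact binomial intervals.

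The 21 gene lists were contractile, matrix and synthetic, S phase, G2 and M phase, actomyosin and focal adhesion, calcium handling and ion channels, growth factor receptors and ligands, proteases and their inhibitors, osteogenic and chondrogenic, inflammatory and chemokine, interferon response, immediate early and dissociation stress, SRF and YAP target, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, cytosolic ribosomal protein, cholesterol synthesis, p53 and senescence, unfolded protein response and secretion, and housekeeping genes. The 12 marker lists covered smooth muscle, fibroblast, endothelial, macrophage, lymphocyte, pericyte, adipocyte, Schwann, erythroid, chondrocyte, striated muscle, and mesothelial and epithelial cells. Named genes were the 12 highest and 12 lowest log2 ratios among genes with a read in at least 50% of the cells of the higher passage, higher there in at least 70% of cell pairs and with 1 direction whichever cell was left out. They also included the members of each list with the highest means and the highest and lowest ratios, set contractile and matrix genes, the 5 genes with the highest CV and the 5 with the highest mean in each passage, and the leading genes of clusters. Lists, this rule, filters, comparisons and most alternatives were chosen before the data were examined. The rule of at least 3 markers at a value of 10 and the rule for naming clusters (at least 2 markers of a type among the 10 leading genes) were set afterwards.

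Similarity of cells was the Spearman correlation over the kept genes. Clusters used log2(value + 1) of the 500 genes with the highest variance, 10 principal components and Ward linkage, with 2 to 6 clusters by mean silhouette, and clusters of fewer than 3 cells were treated as single cells. Alternatives were other pseudocounts (0.1 and 10), filters, scalings (counts per total and TMM), summaries over cells, thinning, removal of the 25% of cells with the fewest genes, and each cell left out in turn. Further checks matched cells of the passages on reads to within 10%, and compared G2 and M phase with housekeeping reads within a cell. In simulated data with true log2 ratios of -3, -1, 1 and 3 the recovered medians were -2.74, -0.91, 1.00 and 2.88, with the right sign in 100%, 96%, 94% and 100% of genes. Every simulated gene had the same added spread between cells, drawn independently. The shares with the right sign need not hold for genes whose values rest on few cells. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.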

Results

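The study sequenced RNA from single vascular smooth muscle cells (VSMCs), the contractile cells of the vessel wall, taken from the descending aorta of adult male C57Bl6 mice aged 3 to 4 months. The cells were grown in medium with 10% serum and 1% antibiotic and were left undisturbed for 5 days, after which passage 1 cells were detached with trypsin and replated to give passage 2. Cells were captured on a microfluidic system and each became 1 library, 22 at passage 1 and 45 at passage 2. The comparison the design implies is between the passages, and the question was which phenotypes cultured VSMCs take and how alike the cells of a passage are. The labels name no animal or culture for a cell, so each passage counted as 1 sample, and no p-value, standard error or count of changed genes was computed. SDs describe the spread between cells. The library labels of all passage 1 cells carry a different prefix from those of all passage 2 cells, so passage and library set could not be separated. Traction force measurements named in the study design were not analysed here.

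Reads per cell, recovered from the deposited values, ranged from 817021 to 1561129 at passage 1 and from 548419 to 1509589 at passage 2, with totals of 26400274 and 41340350 reads. A median of 8477.5 genes per cell had a read at passage 1 and 7257 at passage 2, so passage 1 cells were deeper and shares of cells with a read carry that gap. Values are normalized counts. The median log2 ratio (passage 2 over passage 1) over all 8682 genes kept was -0.11, against which the ratios below can be read. It was -0.60 with medians over cells and -0.62 with means of log2 values, the baselines for ratios given under those settings.

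Genes of the cell cycle were lower at passage 2 than at passage 1. All 20 G2 and M phase genes measured were lower, with a median log2 ratio of -3.22 (9.32-fold), and so were all 19 measured S phase genes, with a median of -2.69 (6.43-fold). Neither median was reached by any of 10000 random lists of matched expression. Top2a, a topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), averaged 325 ± 468 at passage 1 and 12.3 ± 63.1 at passage 2. Mki67, the proliferation marker, averaged 243 ± 308 and 29 ± 94.4. Rrm2, a subunit of ribonucleotide reductase, averaged 425 ± 433 and 42.9 ± 141, and Mcm7, of the replicative helicase, 130 ± 139 and 4.52 ± 14.4. The cyclin gene Ccna2 differed least of its list, at 93.7 ± 94.4 and 55.6 ± 175. Leaving out passage 2 cell 14 moved the log2 ratio of Top2a from -4.61 to -6.36 and that of Ccna2 from -0.74 to -1.51, and leaving out passage 2 cell 9 moved the G2 and M phase median to -3.88. The same cell moved the log2 ratio of Mki67 from -3.02 to -3.76. Without the cells that had Mki67 or Top2a at 10 the medians were -1.37 for G2 and M phase and -1.96 for S phase, and with medians over cells -4.12 and -5.18. With means of log2 values the S phase median was -3.45. In 15 cells of each passage matched on reads the G2 and M phase median was -2.52, and with a pseudocount of 10 it was -2.55.

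The share of cells with these genes differed in the same direction. Mki67 had a value of at least 10 in 15 of 22 passage 1 cells (68.2%, exact 95% interval 45.1 to 86.1) and in 7 of 45 passage 2 cells (15.6%, 6.49 to 29.5). With any read the shares were 72.7% and 33.3%, and after thinning every cell to 500000 reads they were 72.7% and 26.7%. Top2a reached 10 in 13 of 22 cells (59.1%) and in 6 of 45 (13.3%). Intervals and floors for shares cover the counting of cells only. They leave out differences between animals or cultures, because each passage counts as 1 sample. Intervals on reads take reads as independent, which PCR reads without molecular identifiers are not.

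Contractile genes were higher at passage 2. Of 18 measured members of the list, 17 were higher and the median log2 ratio was 1.51 (2.85-fold), above all 10000 random lists. Acta2, smooth muscle α-actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590 in GRCm38), averaged 824 ± 1221 at passage 1 and 3965 ± 3903 at passage 2, and was higher in the passage 2 cell in 86% of cell pairs. Tagln, transgelin (chromosome 9, 45929619 to 45936058), averaged 355 ± 520 and 1810 ± 1492. Cald1, caldesmon, averaged 980 ± 704 and 2618 ± 1674. The integrin gene Itga8 showed the highest ratio, with 25.7 ± 70.1 and 240 ± 279. Smooth muscle myosin heavy chain, Myh11 (chromosome 16, 14194535 to 14291372), averaged 12.1 ± 43.5 and 47.8 ± 113, and calponin, Cnn1, 3.61 ± 11.5 and 24.6 ± 83.7. Smoothelin, Smtn, averaged 36.2 ± 52.1 and 67.1 ± 90, and Myocd, which encodes a coactivator of contractile genes, 10 ± 43 and 20.1 ± 56.3. Actg2 was the member lower at passage 2, at 36.4 ± 104 and 13.9 ± 51.9, and shares near-identical sequence with other actin genes. The same limit applies to Acta2. Single passage 1 cells carried several of these values. Without passage 1 cell 9 the list median was 2.26 and the log2 ratio of Myh11 moved from 1.90 to 3.5 and that of Actg2 from -1.33 to -0.57. Without passage 1 cell 17 the log2 ratio of Itga8 moved from 3.18 to 3.97, without passage 1 cell 18 that of Cnn1 from 2.47 to 3.28, and without passage 1 cell 14 that of Myocd from 0.94 to 3.51. Without the cells that had Mki67 or Top2a at 10 the list median was 2.11 and the log2 ratio of Myocd -1.50. That removal left 6 passage 1 cells, and cell 14 was among them. It was an endothelial marker cell, with at least 3 of 10 endothelial markers at a value of 10. Without the 25% of cells of each passage with the fewest genes the list median was 2.38.

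**Figure D1:**
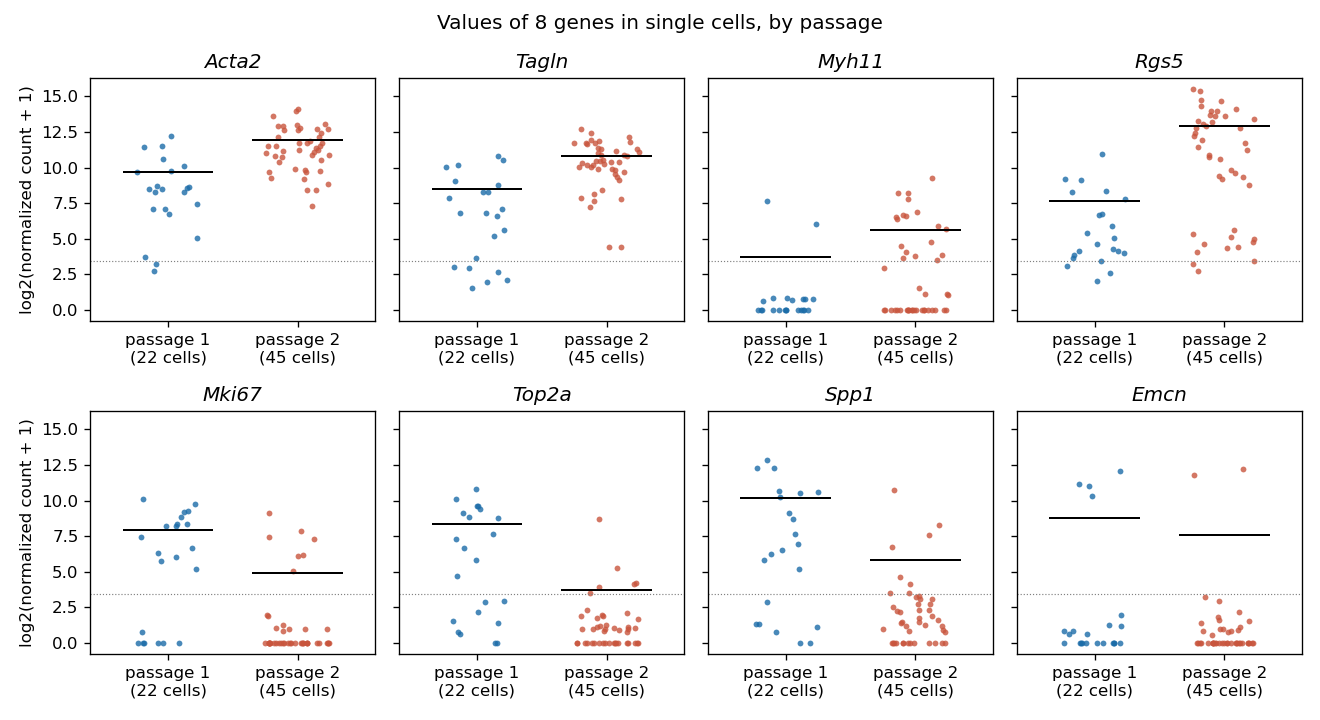
Each point is 1 cell, plotted as log2(normalized count + 1) by passage (22 and 45 cells) with small random sideways shifts. Black bars mark log2(mean + 1) and the dotted line a value of 10. Mki67 reached 10 in 15 passage 1 and 7 passage 2 cells, and Myh11 in 2 and 18.

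Myh11 reached a value of 10 in 2 of 22 passage 1 cells (9.09%, 1.12 to 29.2) and in 18 of 45 passage 2 cells (40%, 25.7 to 55.7), whereas Acta2 reached it in 20 of 22 and 45 of 45. With any read the shares for Myh11 were 40.9% and 51.1%, and after thinning 18.2% and 48.9%. Among 23 marker genes of lymphocytes, erythroid cells and striated muscle, the highest share with any read was 31.8% at passage 1 (Lck) and 33.3% at passage 2 (Cd3d), and the highest share at 10 was 9.09% and 8.89%. The passage 1 share for Myh11 at 10 equals the highest background share, so the share alone does not set Myh11 apart from background at passage 1. The same holds for Cnn1 and Myocd, each at 10 in 2 of 22 passage 1 and 8 of 45 passage 2 cells, with medians of 0 in both passages.

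Matrix and synthetic genes were mostly higher at passage 2, with exceptions. Of 25 measured members, 21 were higher and the median log2 ratio was 1.07 (2.09-fold), above all random lists. Fibronectin, Fn1, averaged 2040 ± 1250 and 4451 ± 2260, and biglycan, Bgn, 2404 ± 978 and 3841 ± 1751. The collagen genes Col1a1 (262 ± 247 and 549 ± 417) and Col3a1 (225 ± 255 and 481 ± 533) were both about the list median. Elastin, Eln, averaged 1.87 ± 6.54 and 44.7 ± 70.1. Against this, osteopontin, Spp1 (chromosome 5, 104435118 to 104441050), averaged 1130 ± 2026 at passage 1 and 55 ± 260 at passage 2 and reached 10 in 15 of 22 and 8 of 45 cells. Versican, Vcan, averaged 75.9 ± 119 and 2.96 ± 12.3. Leaving out passage 2 cell 36 moved the log2 ratio of Spp1 from -4.34 to -5.96, passage 2 cell 11 moved that of Vcan from -4.28 to -5.10, and passage 1 cell 9 moved that of Eln from 3.99 to 4.94. Passage 2 cell 11 was an endothelial marker cell.

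The 12 genes with the highest ratios, among genes with a read in at least 50% of passage 2 cells, higher there in at least 70% of cell pairs and with 1 direction whichever cell was left out, were led by Cpxm2, which averaged 0.429 ± 0.697 and 110 ± 204, Serpina3n, a protease inhibitor, 1.80 ± 4.18 and 183 ± 316, Myom1, of the sarcomere M-band, 0.851 ± 2.47 and 96.6 ± 147, and Cemip, a hyaluronan-binding protein gene, 1.42 ± 4.67 and 105 ± 175. Rgs5, a regulator of G protein signalling found in mural cells, averaged 200 ± 426 and 7608 ± 10752 and took 0.742% of all passage 2 reads. Fmod, fibromodulin, averaged 3.61 ± 12.6 and 152 ± 223, and the convertase gene Pcsk5 26.7 ± 90.2 and 512 ± 968. Itga11, 1500015O10Rik and Rasl12 had log2 ratios of 5.09, 4.91 and 4.36. Aoc3 and Scara5 had 1 and 2 reads at passage 1 and 1578 and 1500 at passage 2, ratios of summed reads, each per total reads of its passage, of 1008 (181 to 39828) and 479 (132 to 3959). Over passage 2 cells the medians were 1.16 (Cpxm2), 5.29 (Serpina3n), 1.94 (Aoc3), 0.97 (Scara5), 1.88 (Itga11), 0.82 (1500015O10Rik) and 0.94 (Rasl12). At passage 1 they were 0. These genes reached a value of 10 in 7 (Scara5) to 18 (Serpina3n) of 45 passage 2 cells. Their ratios of means therefore rest on part of the passage 2 cells. Passage 2 medians were higher for Pcsk5 (12.1), Myom1 (23.9), Cemip (27.6), Fmod (46.3) and Rgs5 (2811). Leaving out passage 1 cell 17 moved the log2 ratio of Cemip from 5.46 to 6.21, and leaving out passage 1 cell 15 moved those of Rgs5 and Pcsk5 from 5.24 to 6.01 and from 4.21 to 5.85. Fmod moved from 5.05 to 6.29 without passage 1 cell 19, 1500015O10Rik to 4.10 without passage 2 cell 21 and Rasl12 to 3.57 without passage 2 cell 38.

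At the other end, the 12 genes with the lowest ratios by the same rule were led by Kif20b. This mitotic kinesin gene averaged 199 ± 218 at passage 1 and 0.734 ± 4.12 at passage 2, and Fignl1, of DNA repair, 91.8 ± 121 and 0.417 ± 0.954. Ncapg2 of condensin averaged 154 ± 210 and 2.44 ± 11.9, and the histone chaperone gene Asf1b 88.2 ± 93.0 and 1.2 ± 4.68. Cenpi, Palmd, Esco2, Gins3, Bub1b, Kif15, Ddias and Cdc45 had log2 ratios between -5.57 and -4.87. Their medians over passage 1 cells were 6.32, 0.680, 2.84, 0.943, 1.52, 20.4, 1.73 and 2.75 in that order, against 0 at passage 2. The ratios of means for these genes therefore rest on part of the passage 1 cells. Without passage 2 cell 9 the log2 ratio of Kif20b moved from -6.85 to -7.48, and without passage 2 cell 8 that of Ncapg2 from -5.49 to -6.51. Cenpi moved to -4.88 without passage 1 cell 18, Palmd to -4.65 without passage 1 cell 13, Esco2 to -4.36 without passage 1 cell 12, Bub1b to -5.82 without passage 2 cell 28 and Ddias to -5.57 without passage 2 cell 41. Passage 1 cells 12 and 13 and passage 2 cell 8 were endothelial marker cells. Without the cells that had Mki67 or Top2a at 10, which left 6 and 35 cells, the log2 ratios of Cenpi (0.48), Esco2 (0.14), Kif15 (0.99) and Ddias (0.97) were above 0.

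Immediate early and dissociation-stress genes were higher at passage 2 in 15 of 16 members, with a median log2 ratio of 1.88, above all random lists. The growth-arrest gene Btg2 averaged 278 ± 457 and 1816 ± 1385, Egr1 1367 ± 1246 and 2369 ± 1843 and the small heat shock protein gene Hspb1 0.995 ± 2.04 and 12.2 ± 17.6, while Klf4 averaged 190 ± 236 and 157 ± 211. Inflammatory and chemokine genes were higher in 10 of 12 members, with a median of 1.05 (percentile 99.9), which was 0 with medians over cells and 1.65 without the endothelial marker cells. Il6 averaged 1.72 ± 5.28 and 101 ± 248 and reached 10 in 2 of 22 cells, the highest background share, and in 13 of 45, and Vcam1, an adhesion molecule gene, averaged 603 ± 1096 and 235 ± 422. Leaving out passage 1 cell 6 moved the log2 ratio of Il6 from 5.23 to 5.89. Leaving out passage 1 cell 13, an endothelial marker cell, moved that of Vcam1 from -1.35 to -0.72. The p53 and senescence list had a median of 0.66 (percentile 98.6, 8 of 11 higher) with Igfbp4 at 33.1 ± 87.8 and 372 ± 578 and Glb1 at 69.2 ± 140 and 27.2 ± 76.4. Its median was -0.09 with medians over cells and -0.08 with means of log2 values, and 1.33 without endothelial marker cells. With medians over cells and means of log2 values the all-gene medians were -0.60 and -0.62, lower than those of this list. Without passage 1 cell 13 the log2 ratio of Igfbp4 moved from 3.45 to 4.55, and without passage 1 cell 5 that of Glb1 from -1.32 to -0.58. The interferon response list had a median of 0.78 (percentile 96.7, 5 of 7 higher), within the middle 95% of random lists, and of 0 with medians over cells.

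Genes of the SRF and YAP pathways had a median log2 ratio of 0.63 (percentile 98.7, 10 of 14 higher), with Fhl2 at 49.7 ± 85.3 and 330 ± 479. Actomyosin and focal adhesion genes had a median of 0.52 (percentile 97.4, 17 of 22 higher), within the middle 95% of random lists, with the light chain gene Myl12a at 521 ± 208 and 1413 ± 531 and higher in 96% of cell pairs. Glycolysis genes were lower in 12 of 14 members with a median of -0.64 (percentile 0.41). Pyruvate kinase, Pkm, averaged 728 ± 450 and 224 ± 209, while hexokinase 2, Hk2, averaged 196 ± 234 and 668 ± 793. Cholesterol synthesis genes had a median of -0.62 (percentile 1.68, 11 of 14 lower), or -1.97 with medians over cells, with Hmgcs1 at 669 ± 722 and 420 ± 673.

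Besides the actomyosin, interferon response and fibroblast lists, those whose medians lay within the middle 95% of random lists were growth factor receptors and ligands (0.37), osteogenic and chondrogenic (0.41), mitochondrially encoded (0.18), proteases and their inhibitors (0.01), housekeeping (-0.03), cytosolic ribosomal protein (-0.04), nuclear oxidative phosphorylation (-0.07), calcium handling and ion channels (-0.13) and unfolded protein response and secretion (-0.16). The osteogenic median was -0.27 with the stricter filter, -0.28 with medians over cells and 1.02 with no filter, and the growth factor median -0.087 with either filter change. With TMM scaling the signs of the oxidative phosphorylation (0.047), ribosomal (0.082) and housekeeping (0.11) medians turned. Single members still differed. The Notch ligand gene Jag1 averaged 273 ± 305 and 1882 ± 1564, the receptor gene Notch3 1.33 ± 4.34 and 27.4 ± 59.7, and Igf1, a growth factor gene, 132 ± 218 and 7.48 ± 34.2. Cystatin C, Cst3, averaged 433 ± 213 and 2825 ± 1804 and was higher in 95.6% of cell pairs, while Mmp3 averaged 62.8 ± 144 and 3.05 ± 19.8. Without passage 2 cell 7 the log2 ratio of Igf1 moved from -3.97 to -5.19, and without passage 2 cell 21 that of Mmp3 from -3.98 to -5.86. Without the cells that had Mki67 or Top2a at 10 the log2 ratio of Igf1 was 3.18 and the growth factor median 1.45.

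**Figure D2:**
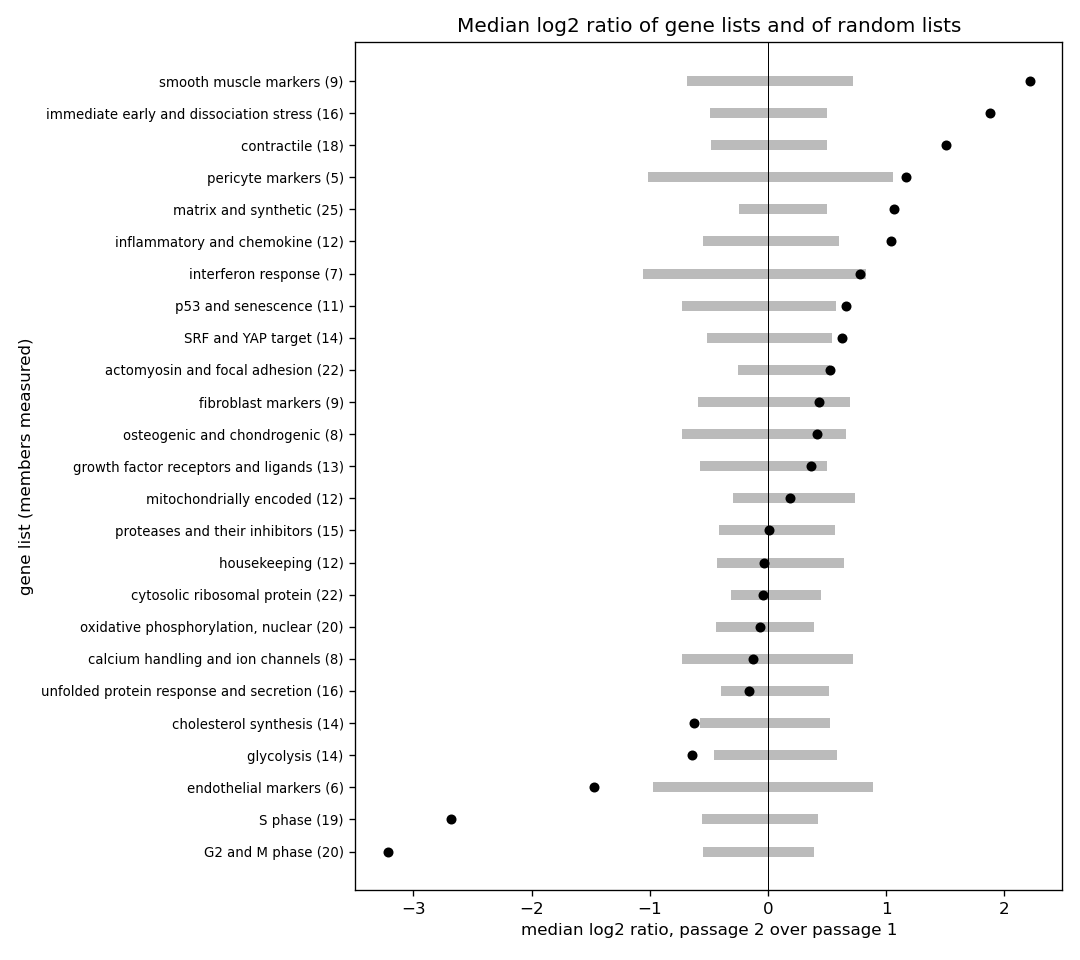
Points are the median log2 ratio (passage 2 over passage 1) of each gene list over its measured members, whose number is in parentheses, and grey bars are the middle 95% of 10000 random lists matched on mean expression. G2 and M phase (-3.22) and S phase (-2.69) lie lowest, and the smooth muscle marker list (2.22) and the immediate early list (1.88) highest.

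Endothelial markers were lower at passage 2, while the fibroblast median lay within the middle 95% of random lists. Smooth muscle markers, all 10 of which are also in the contractile list, were higher at passage 2 in 9 of 9 measured members, with a median log2 ratio of 2.22 (above all random lists), and at least 3 of the 10 reached a value of 10 in 15 of 22 passage 1 cells (68.2%, 45.1 to 86.1) and 44 of 45 passage 2 cells (97.8%, 88.2 to 99.9). Endothelial markers had a median of -1.47 (percentile 0.13). At least 3 of 10 reached a value of 10 in 5 of 22 passage 1 cells (22.7%, 7.82 to 45.4) and in 2 of 45 passage 2 cells (4.44%, 0.543 to 15.1), with overlapping intervals. The median of this list was -2.64 without passage 2 cell 8, -0.73 without passage 1 cell 13 and -0.17 without every such cell. Pericyte markers had a median of 1.17 (percentile 98.3), or 0.47 without the cells that had Mki67 or Top2a at 10, 0 with medians over cells and 1.79 with no filter, and fibroblast markers 0.43 (percentile 89.6), which was 1.13 without passage 1 cell 13 and -1.25 with medians over cells. At least 3 pericyte markers were reached in 31.8% (13.9 to 54.9) of passage 1 and 40% (25.7 to 55.7) of passage 2 cells, whose intervals overlap, and at least 3 fibroblast markers in 72.7% (49.8 to 89.3) and 64.4% (48.8 to 78.1). No cell reached 3 markers of macrophages, lymphocytes, adipocytes, Schwann cells, erythroid cells, striated muscle or mesothelium and epithelium, which by a floor of 3 cells allows a share of up to 13.6% of passage 1 and 6.67% of passage 2 cells (exact upper limits 15.4% and 7.87%), and 1 passage 2 cell reached 3 chondrocyte markers. Too few members of these last 8 lists were measured for a list median.

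**Figure D3:**
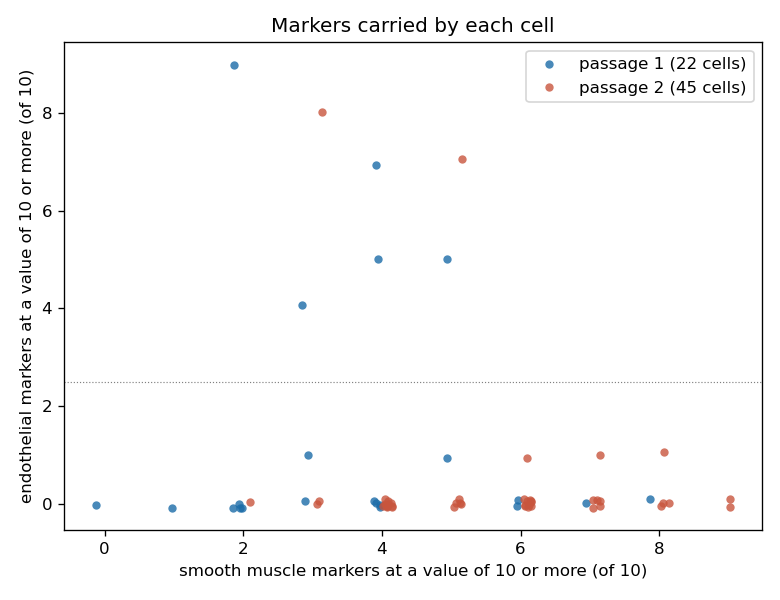
Each point is 1 cell, with the number of smooth muscle markers at a value of 10 or more (of 10) on the horizontal axis and of endothelial markers (of 10) on the vertical axis, with small random shifts. The 5 passage 1 and 2 passage 2 cells above the dotted line reached at least 3 endothelial markers.

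The endothelial marker cells were passage 1 cells 11, 12, 13, 14 and 16 and passage 2 cells 8 and 11. They were selected on a list that holds Emcn and Cdh5, so their values describe the selection. Emcn, endomucin, ranged from 0 to 4269 in the 5 passage 1 cells and from 3605 to 4738 in the 2 passage 2 cells, against highest values of 2.89 and 8.48 in the other cells of each passage. Cdh5, VE-cadherin, ranged from 115 to 868 and from 766 to 784, against 2.93 and 4.24. These cells also had Acta2, with a median of 408 against 307 in the other 17 passage 1 cells and 640 against 2894 in the other 43 passage 2 cells. Tagln was lower in these cells in both passages, with medians of 49.1 against 109 and 127 against 1393. So was Myl9, at 28.3 against 59.8 and 5.49 against 305. Captures of more than 1 cell were not ruled out. Reads per cell of the endothelial marker cells had medians of 1222934 and 764940, against 1231605 and 886710 in the other cells. The G2 and M phase median was -3.48 and the contractile median 1.57 without these cells.

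Contractile and matrix genes were detected in the same cells, but Col1a1 reached 10 in 86.4% and 93.3% of cells, so that joint counts with it were near those of independent genes. Acta2 and Col1a1 both reached a value of 10 in 17 of 22 passage 1 cells (77.3%, 54.6 to 92.2) and 42 of 45 passage 2 cells (93.3%, 81.7 to 98.6). Each of the 18 passage 2 cells with Myh11 at 10 also had Col1a1 at 10, as did the 2 at passage 1, a count at the background share. Acta2 and Mki67 both reached 10 in 14 of 22 cells (63.6%) and 7 of 45 (15.6%). Cnn1 and Spp1 both reached it in 1 cell of each passage, and Myh11 and Mki67 in 1 of 22 and 3 of 45. With any read, Myh11 and Col1a1 were found together in 40.9% and 51.1% of cells, Acta2 and Col1a1 in 95.5% and 97.8%, Cnn1 and Spp1 in 13.6% and 20%, Myh11 and Mki67 in 31.8% and 11.1%, and Acta2 and Mki67 in 72.7% and 33.3%.

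**Figure D4:**
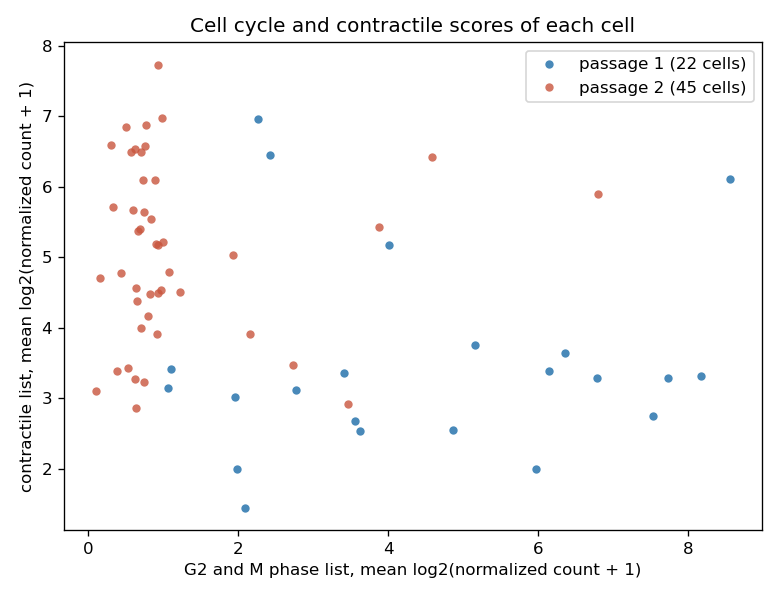
Each point is 1 cell, plotted by its mean log2(normalized count + 1) over the measured G2 and M phase genes (horizontal) and contractile genes (vertical). The G2 and M phase score exceeded 2 in 18 of 22 passage 1 cells and 6 of 45 passage 2 cells, and the contractile score ranged from 1.45 to 6.96 and from 2.86 to 7.73.

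Cells of a passage were more alike than cells of different passages. Over the 8682 genes the median Spearman correlation, taken across genes, which are not independent replicates, was 0.451 within passage 1 (231 pairs), 0.439 within passage 2 (990 pairs) and 0.396 between the passages (990 pairs). Over genes with a mean of at least 100 the medians were 0.462, 0.386 and 0.324.

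Contractile genes had a higher median coefficient of variation (CV) between cells than housekeeping genes, in lists not matched on mean expression. The median was 1.84 at passage 1 (16 members) and 1.68 at passage 2 (18 members). It was 0.464 and 0.5 for housekeeping and 0.344 and 0.422 for ribosomal protein genes. Other lists varied as much, such as inflammatory genes (1.88 and 2.18). The highly expressed contractile gene Cald1 had CVs of 0.718 and 0.639. For G2 and M phase genes the CV was 1.54 over 20 members at passage 1 and 3.20 over the 12 with a mean of at least 10 at passage 2, so the gene sets differ, and the SD of the list score 2.40 and 1.26. Among genes with a mean of at least 100 and a read in at least 50% of the cells of the passage, the highest CVs at passage 1 belonged to Ctla2a (3.91), Akr1c18 (3.62), Nek1 (3.00), Cd34 (2.88) and Igfbp5 (2.64), and at passage 2 to Tnfrsf26 (5.35), Ctla2a (5.02), Cd93 (4.62), Gpx3 (3.72) and Naa15 (3.36). Single cells moved the log2 ratio of each of these genes by over 1.5-fold. Without passage 1 cells it moved from -0.23 to 2.27 for Ctla2a (cell 13), from -5.05 to -2.98 for Akr1c18 (cell 21), from -1.49 to -0.10 for Nek1 (cell 14), from -4.20 to -3.03 for Cd34 (cell 12) and from -0.67 to 0.41 for Igfbp5 (cell 19). Of these, cells 12, 13 and 14 were endothelial marker cells. Without passage 2 cell 8, also an endothelial marker cell, the log2 ratio moved from -1.81 to -4.02 for Tnfrsf26 and from -1.0 to -2.19 for Cd93. Without passage 2 cell 15 it moved from 4.55 to 3.43 for Gpx3 and from -0.41 to -1.36 for Naa15. Passage 1 cell 21 (4017 genes with a read, 25.3% of reads in its 50 highest genes) and passage 2 cell 15 (4754 genes, 31.2%) were among the 3 cells with the fewest genes. Genes with the highest means included Actb (6332 ± 2160 and 9877 ± 3447), Malat1 (4141 ± 2166 and 9718 ± 4728), Fstl1 (5306 ± 2538 and 7906 ± 3869) and mt-Co3 (9158 ± 2261 and 8616 ± 4267).

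Clusters within a passage were weakly separated, with mean silhouettes of 0.206 for 6 clusters at passage 1, where 1000 genes in place of 500 gave 2 clusters, and 0.221 for 4 clusters at passage 2. At passage 1, a cluster of 3 cells led by Sema3a and Myh11 was smooth muscle-like by the naming rule, with a mean Acta2 of 2659. A second cluster of 3 cells was led by Sele and held 3 of the endothelial marker cells, and 10 cells formed a cluster led by Gpr39 and Cenpi in which every cell had Mki67 or Top2a at 10. Both stayed unnamed. The other 6 cells fell in pairs and were treated as single cells. At passage 2, 30 cells formed a cluster led by Fgf7 and Gpc3 with a mean Rgs5 of 11223, and 8 cells a cluster led by Apol6 and Dsp with a mean Rgs5 of 310, both unnamed. A cluster of 5 cells led by Emcn and Ctla2a was endothelial-like by the rule, though only 2 of its cells reached 3 endothelial markers, and 2 cells were treated as single cells. With both passages clustered together, 16 passage 1 cells shared a cluster with no passage 2 cell, and 38 passage 2 cells fell in 2 clusters with no passage 1 cell.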

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

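The removals of endothelial marker cells and of cells with Mki67 or Top2a at 10 were chosen after the data were seen. No paired analysis was possible because the labels name no animal or culture that links a passage 1 cell to a passage 2 cell. A value moved when it shifted by over 1.5-fold, and reversed when its sign turned and the reported value was at least 1.5-fold. Of 398 values of 25 lists, 366 did neither, 30 moved and 2 reversed, and of 2100 values of 133 named genes the numbers were 1753, 332 and 15. With medians over cells 65 of the 133 named genes moved and 2 reversed, and with means of log2 values 65 moved. Counting every turn of sign, also from reported values below 1.5-fold, gives 25 values of 10 lists and 58 values of 33 genes. Scaling by median ratio equals the deposited scaling and so tests nothing. TMM moved the median log2 ratio of all genes from -0.11 to -0.00, and no list moved by over 1.5-fold with TMM or counts per total, though TMM turned the signs of 3 lists near 0 and counts per total that of the protease list. Thinning keeps the expected ratio of scaled means, so it tests only the shares. The counts above include median ratio scaling and thinning, and in each of these all 25 lists and all 133 named genes stayed unmoved. Except where stated, the cause was not tested.

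With medians over cells the list medians were -5.18 (S phase), -4.12 (G2 and M phase), -0.28 (osteogenic), 0 (inflammatory, interferon and pericyte), -1.97 (cholesterol), -0.092 (p53, reversed), -1.25 (fibroblast) and -0.19 (endothelial), and the log2 ratios of Ifit2 (-0.12) and Cd93 (0.19) reversed. With means of log2 values they were -3.45 (S phase), -0.078 (p53, reversed) and -0.84 (fibroblast). The all-gene median itself was -0.60 with medians over cells and -0.62 with means of log2 values. Moves and turns of sign under these settings hold that common shift. A pseudocount of 10 gave -2.55 for G2 and M phase, which shrinks ratios by construction. Without a filter the osteogenic median was 1.02 and the pericyte median 1.79, and with the stricter filter the osteogenic median was -0.27.

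Without cells that had Mki67 or Top2a at 10 the medians were 2.11 (contractile), -1.96 (S phase), -1.37 (G2 and M phase), 1.45 (growth factor) and 0.47 (pericyte). The log2 ratios of Cenpi (0.48), Esco2 (0.14), Kif15 (0.99), Ddias (0.97), Myocd (-1.50), Igf1 (3.18), Col11a1 (0.25) and S100b (0.21) reversed, with 6 passage 1 cells left. Passage 1 cell 14, an endothelial marker cell on which the passage 1 mean of Myocd rested, was among these 6. This removal selects on cell cycle genes, so it shrinks their difference between the passages by construction. Without endothelial marker cells the medians were 1.65 (inflammatory), 1.33 (p53), 1.18 (fibroblast) and -0.17 (endothelial), and Pxn (0.30), Cd34 (1.18), Emcn (0.26) and Vwf (0.11) reversed. Without the 25% of cells with the fewest genes the contractile median was 2.38.

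Leaving out each cell in turn, the contractile median ranged from 1.42 to 2.26, G2 and M phase from -3.88 to -2.96, fibroblast from 0.20 to 1.13 and endothelial from -2.64 to -0.73, and the log2 ratio of Igfbp5 from -0.93 to 0.41, the latter without passage 1 cell 19. Medians near 0 changed sign on a single cell for the calcium (0.01 without passage 1 cell 7), unfolded protein (0.04 without passage 1 cell 14), ribosomal and housekeeping (0.01 each without passage 1 cell 21) and protease lists (24 cells), so no direction is given for these.

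At a value of 10, Myh11 with Col1a1 was in 9.09% and Myh11 with Mki67 in 4.55% of passage 1 cells, and Cnn1 with Spp1 in 2.22% and Acta2 with Mki67 in 15.6% of passage 2 cells. After thinning the first 3 were 18.2%, 13.6% and 8.89%. Acta2 with Col1a1 was in 100% of passage 2 cells without endothelial marker cells. Over genes with a mean of at least 100 the median correlation was 0.386 within passage 2 and 0.324 between passages, and 1000 genes gave 2 clusters at passage 1.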

Other observations

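The tests with cells matched on reads, of reads within a cell, of the library sets and of carried-over reads, the removals of endothelial marker cells and of cells with Mki67 or Top2a at 10, and the Rgs5 threshold were chosen only after the result was seen.

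Rgs5 separated the cells of passage 2. A value of at least 100 was found in 33 of 45 passage 2 cells (73.3%, exact 95% interval 58.1 to 85.4) and in 7 of 22 passage 1 cells (31.8%, 13.9 to 54.9). Medians were 2811 and 28, and in 1 passage 2 cell Rgs5 took 4.89% of reads. The 2 passage 2 endothelial marker cells had Rgs5 values of 24.0 and 30.2, against a median of 3359 in the other 43. Low values were not confined to them, as 12 of 45 passage 2 cells were below 100. At passage 1 the medians went the other way, at 57.46 in the 5 endothelial marker cells and 18.04 in the other 17.

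For the lower cell cycle genes at passage 2, 15 cells of each passage were matched on reads to within 10%. The G2 and M phase median log2 ratio was then -2.52 (-3.67 to -2.17 with each match left out in turn), which argues against depth as the whole cause. That range is not a sampling interval, so it cannot tell whether the shift from -3.22 over all cells reflects which cells were kept. Whether depth had a part cannot be told. Without endothelial marker cells the G2 and M phase median was -3.48 (-4.15 to -3.19), which argues against those cells. The log2 ratio of G2 and M phase to housekeeping reads of the same cell, in which the authors' factor cancels, differed between passage medians by -5.38 (-5.48 to -5.29). This argues against the scaling but is not separate evidence. The scaled medians of -3.22 (G2 and M phase) and -0.03 (housekeeping) already implied such a gap. No passage (0) held both library label prefixes, so passage and library set cannot be told apart for this pattern, and a difference between passages in culture stays open, untested.

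The higher contractile genes at passage 2 could reflect which cells were captured. The median log2 ratio was 1.57 (1.42 to 2.24) without endothelial marker cells and 2.11 (1.79 to 2.97) without cells that had Mki67 or Top2a at 10, which argues against either kind alone as the whole cause. The second removal left 6 passage 1 cells, 2 of them endothelial marker cells, and both kinds were not removed together, so their joint effect stays open. In the cells matched on reads the contractile median was 0.99 (0.81 to 1.90), which argues against depth as the whole cause. That range is not a sampling interval, so it cannot tell whether the shift from 1.51 over all cells reflects which cells were kept. Whether depth had a part cannot be told. Library set and passage are confounded here as well, and a difference between passages in culture was not tested.

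Most cells had few reads of endothelial genes, and reads carried over between libraries could be the source. Over the 6 markers with at least 500 reads, a filter set after the values were seen, the chi-square per degree of freedom was 136, and 13.5 after division by the variance to mean ratio of the reads between cells (10.1), since reads without molecular identifiers are not independent. The 95% point of F is 2.31, and the value without the highest cell of each marker was 33.3. Emcn had 0.908 reads in other cells per 1000 in endothelial marker cells, against 76.6 for Egfl7 and 55.1 for Vwf, which argues against a single proportion. Proportions that differ between libraries and low expression stay open, and no biological explanation was tested.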
